A study of Mus musculus with 120 samples.

How the data were processed

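The series measured RNA in the livers of 10 Collaborative Cross mouse strains, inbred lines that each carry a different mixture of the genomes of several founder strains. Per the labels' protocols, mice received for 12 weeks either a fattening diet rich in fat and sucrose (HF/HS) or a matched control diet low in fat and with less sucrose. The HF/HS diet took 42% of its energy from milkfat, held 0.2% cholesterol and was more than 30% sucrose. Livers were flash frozen, total RNA was extracted with miRNeasy kits, and libraries were prepared from 500 ng. Both a ribosomal-RNA-depletion kit and an mRNA kit are named in the labels' protocols, without saying which library was made with which. The labels name 120 libraries: 10 strains, 2 sexes and 2 diets, with 3 libraries in each of the 40 groups. The series text speaks of triplicates, and no label says that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries.

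All values came from the deposited table of 24883 rows and 120 columns, 1 column per library. Per the submitters' processing notes, reads were mapped to mm10, and TopHat2 2.1.1, Bowtie2 2.2.5.0 and Cufflinks 2.2.1 were named with no role or order. The table holds FPKM-like values that the authors rescaled, since the 75th percentile over all rows was between 9.992 and 10 in every library. The formula of that scaling, the annotation release and any filter were not given in the sources used here. The deposited values are not read counts, so the sequencing depth of each library is unknown, and no counting interval or floor is given. A value of 0 can also mark a gene that could not be estimated: Alb, the most abundant liver transcript, was listed at 0 in 104 of the 120 libraries. In the table, 821 rows share a symbol with another row, and 1 row with a missing value was left out.

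The groups came from the labels. The columns of CC040 female control 3 and CC040 female HF/HS 1 held equal values in all 24883 rows, so at least 1 of them carries a wrong label. Both were left out, which left 118 libraries. This departs from the design, was decided after the data were examined, and a fit with all 120 columns as labelled was added as an alternative.

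Genes with a mean of at least 1 over the 120 libraries were tested, 12205 in all. Values were used as log2(value + 1). The test was limma 3.58.1 in R 4.3.3, with 1 mean for each of the 40 groups, a spread shared by all libraries, and a prior for the spread that followed mean expression and was robust. Contrasts were taken over these means: HF/HS minus control over the 20 strain-sex groups, in each sex, in each strain and in each strain-sex group, male minus female diet effect, and male minus female on each diet. F tests on 9 contrasts compared the diet effects of the strains and the strains on the control diet. All tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the genes tested. A gene is called at an adjusted p under 0.05, and "rose" and "fell" are used for called genes. The log2 differences are means over groups with equal weight. Means with SD are over the libraries' values, so their SD includes the differences between strains.

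For gene groups, 33 lists of pathway genes and cell type markers were written from general knowledge, with the tests and the alternatives, before the data were examined. Of these, 31 had at least 3 tested members and were tested with limma's camera at its preset inter-gene correlation of 0.01, and again with an estimated correlation. Camera asks whether the members ranked higher or lower than other genes. Genes were named by a rule. Outside the lists it passed over rows with a repeated symbol and symbols of the Gm-number, Rik, -ps, LOC, clone-number, March, Sept and Dec kinds. It took the 10 largest changes per direction over all, with that sign in at least 15 of 20 groups. It also took the 5 largest per direction in each sex, with that sign in at least 8 of 10 strains, and the 5 largest per direction for the difference between the sexes and for sex on the control diet. It took the 10 lowest p of each F test, the 2 largest per direction in each strain with the same sign in both sexes, and up to 4 members with the lowest p from each list. For falls, these sign rules only asked that the difference was not a rise, so groups without any difference counted as falls. Genes named outside it are said to have been chosen after their values were seen. Of the genes this rule took, 1 for the difference between the sexes and 1 list member are not reported here, and the counts, list tests and other summaries include them. Coordinates are those of the table, on mm10 and counted from 1.

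The alternatives planned were pseudocounts of 0.1 and 5, no filter and a filter 5 times higher, quantile normalization, size factor scaling, a prior without trend, the library number as a block over all groups or within strain and sex (statmod 1.5.0), the strain as the unit, each strain's own libraries alone, and 12 settings that each left out 1 of the 3 library numbers from 1 sex and diet in all strains. Those added after seeing the data were all 120 columns, no rows with a 0 beside a value of at least 20 in the same group, no CC003 and CC060 libraries, no libraries of the largest residual spread, and library weights. For each count of genes, 100 splits of the same libraries were drawn, or 60 where no more exist. The pipeline was tested on simulated data: of 100 genes changed by 0.5 on the log2 scale, 97% were called for the effect over all strains and 64% for that in CC011, with 13 false calls in each. In single strain-sex groups 41% were called in CC013 females and 48% in CC060 males. The simulated noise was normal and independent, with 1 SD per gene for all libraries. The residual spread of the real libraries ran from 0.26 to 0.742, so these false calls do not give the level in the real counts. Relations over strains used permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Left out were the 2 identical columns, genes below the filter, and a test of read counts, since counts were not used here.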

Results

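Liver RNA was measured in 120 sequencing libraries from 10 Collaborative Cross strains (CC003, CC011, CC013, CC019, CC032, CC040, CC041, CC042, CC043 and CC060). Each strain had females and males on the control diet and on the HF/HS diet, with 3 libraries in each of the 40 groups. After 2 identical columns were left out, CC040 had 5 control and 5 HF/HS libraries, every other strain had 6 and 6, and each diet had 59 libraries. Females had 29 libraries on each diet and males 30. The depth of the libraries is unknown. Xist, the RNA that silences an X chromosome in females, had values of 28.5 to 135 in female and of 0.00857 to 2.1 in male libraries. Of 4 Y-linked genes, Uty, Kdm5d and Eif2s3y had no overlap between the sexes, and Ddx3y had 1 overlapping library.

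The libraries of CC003 and CC060 differed in kind from the others. CC003 libraries summed to 3192062 to 4629890 units and other strains' libraries to 926949 to 1986963, and 41.5% to 45.1% of genes were at 0 in CC003 against 30.6% to 37.9% elsewhere. The median of Snord104, a small nucleolar RNA, was 755300 in CC003, 0 in CC060 and 25040 to 53200 in the other 8 strains. In CC060 the medians of RNAs without a poly(A) tail were low. Rmrp was at 2.02 (10280 to 19200 in the other 8), Rpph1 at 1.37 (22820 to 44530) and the histone gene Hist1h4h at 16.0 (170 to 262). Malat1 was at 68.1 in CC060 and at 761 to 1687 in the other 8. For these 2 strains, differences from other strains cannot be told apart from library preparation. Diet was compared within each strain.

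The main question was how the liver transcriptome responds to the HF/HS diet across strains and sexes. All 24 tested genes of cholesterol synthesis and uptake fell, and 12 of 18 tested genes of lipid droplets and storage rose. Sqle, the squalene epoxidase gene, fell by 2.72 ± 0.142 (log2, SE; adjusted p = 8.31e-28, limma), from 65.4 ± 34.1 to 15.02 ± 20.5 (SD, n = 59 and 59 libraries). Cd36, which encodes a fatty acid transporter, rose by 1.10 ± 0.0643 (adjusted p = 2.41e-25), from 51.4 ± 34.6 to 109 ± 62.4. Both changed in the same direction in all 20 strain-sex groups. Of 12205 genes tested, 2095 rose and 1880 fell, which is 32.6% of the genes. With the strain as the unit, 2072 genes were called instead of 3975.

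Among the genes the rule could name, the largest rise was that of Adam11, which encodes a membrane protein of the disintegrin family. It rose by 1.67 ± 0.0647 (adjusted p = 6.45e-37), from 2.25 ± 2.26 to 12.2 ± 16.5, with the same sign in 19 of 20 groups (chromosome 11, 102761439 to 102780262). Cyp3a11, a drug-metabolising cytochrome P450 gene, rose by 1.54 ± 0.131 (adjusted p = 1.38e-16), from 1057 ± 1126 to 2407 ± 1463 (chromosome 5, 145854607 to 145879854). Mogat1, which encodes an enzyme of diacylglycerol synthesis, rose by 1.24 ± 0.0844 (adjusted p = 1.31e-21), from 1.20 ± 1.12 to 5.58 ± 4.98, in all 20 groups (chromosome 1, 78511060 to 78538173). Ly6d rose by 1.44 ± 0.177 (adjusted p = 3.08e-10) and the keratin gene Krt23 by 1.14 ± 0.149 (adjusted p = 2.01e-09). Serpinb1a rose by 1.06 ± 0.0820 (adjusted p = 9.68e-19), and Vnn1 by 0.99 ± 0.116 (adjusted p = 5.82e-11). The lipid droplet gene Cidec rose by 0.98 ± 0.121 (adjusted p = 2.58e-10), but not with the strain as the unit (adjusted p = 0.0651). Lcn2, an acute-phase gene, rose by 1.04 ± 0.242 (adjusted p = 0.000449). Its HF/HS mean of 480 ± 2800 rests on 1 library, CC011 female HF/HS 1, with a value of 21580, but it was called in each of the 12 leave-out settings (highest adjusted p = 0.00601, without female control 1).

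Of the genes the rule took for the largest falls, most encode enzymes of cholesterol synthesis. Idi1 fell by 2.09 ± 0.110 (adjusted p = 8.31e-28), from 119 ± 69.1 to 28.6 ± 25.0 (chromosome 13, 8885606 to 8892396). Cyp51 fell by 1.91 ± 0.108 (adjusted p = 5.86e-26), from 68.2 ± 31.4 to 19.2 ± 14.99, and Fdps by 1.88 ± 0.137 (adjusted p = 6.68e-20), from 370 ± 157 to 118 ± 91.5. Msmo1 fell by 1.80 ± 0.104, Nsdhl by 1.62 ± 0.110 and Mvd fell by 1.501 ± 0.129 (adjusted p = 2.13e-25, 1.73e-21 and 1.93e-16). Fabp5, a fatty acid binding protein gene, fell by 1.59 ± 0.157 (adjusted p = 9.87e-14), from 306 ± 207 to 123 ± 133. The rule also took Snord45c and Snord67, listed at 0 in 108 and 92 of 118 libraries. They fell at an adjusted p of 0.0332 and 0.0325, and with the strain as the unit neither was called (adjusted p = 0.2 and 0.0638). Snord45c was also not called in 9 of the 12 leave-out settings (0.0519 to 0.0923), and Snord67 not in 5 (0.0608 to 0.115). Snord45c was not called with all 120 columns (0.0508) or without the CC003 and CC060 libraries (0.069), and Snord67 not with library weights (0.0527).

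**Figure D1:**
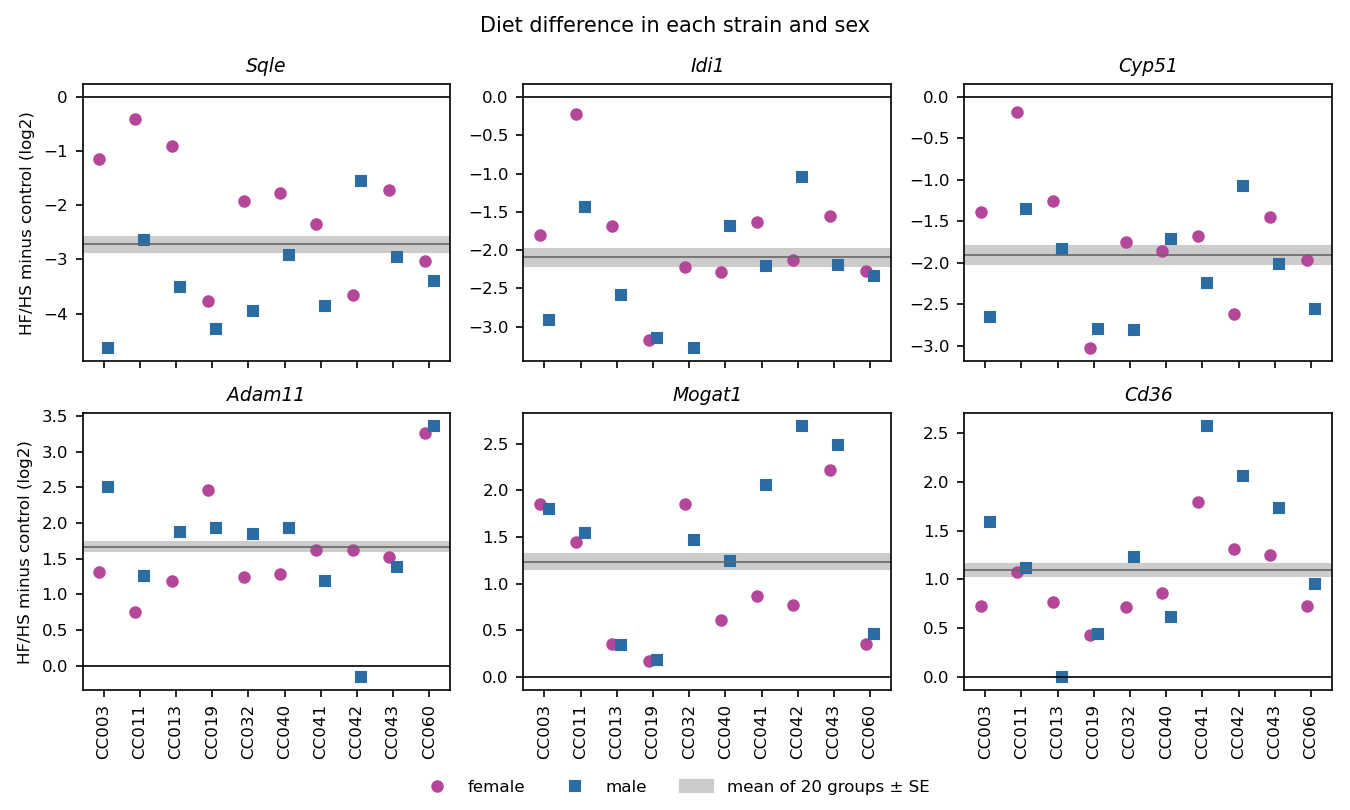
HF/HS minus control (log2) of Sqle, Idi1, Cyp51, Adam11, Mogat1 and Cd36 in each strain, with females as circles and males as squares. The grey band is the mean of the 20 groups ± SE, which for Sqle is -2.72 ± 0.142.

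Of the 24 tested cholesterol synthesis and uptake genes, all 24 fell, over all genes and adjusted over the list alone. Their median was -1.21 (camera adjusted p = 7.47e-57, or adjusted p = 0.000709 with an estimated correlation). In the fatty acid synthesis list 14 of 19 members fell and 1 rose, with the same counts adjusted over the list alone (median -0.48, adjusted p = 8.97e-07). That list was not called with an estimated correlation (adjusted p = 0.404 with an estimated correlation). Acss2 fell by 1.35, Acly by 0.97, Acacb by 0.80 and Fads1 by 0.55, and Srebf1, which encodes a regulator of these genes, rose by 0.42 (adjusted p = 0.00711). In the list of fatty acid oxidation and targets of the receptor PPAR-alpha, 19 of 26 rose and 1 fell, and 21 rose and 1 fell adjusted over the list alone (median 0.22, adjusted p = 1.42e-09, but adjusted p = 0.404 with an estimated correlation). Among its members, Acaa1b rose by 0.91, Aldh3a2 by 0.80 and Acadm by 0.33, and Pdk4 fell by 0.32 (adjusted p = 0.0372). In the lipid droplet and storage list 12 of 18 rose, 12 also adjusted over the list alone (median 0.30, adjusted p = 8.8e-10, and adjusted p = 0.00347 with an estimated correlation). These included Fitm1 with 0.94 and Pparg, which encodes a regulator of lipid storage, with 0.73 ± 0.0609 (adjusted p = 3.21e-17). Of 9 targets of the sterol receptor LXR, 6 rose, and 7 adjusted over the list alone (median 0.20, adjusted p = 9.49e-06, and adjusted p = 0.00166 with an estimated correlation). The sterol transporter genes Abcg5 and Abcg8 rose by 0.72 and 0.54, Abcg1 by 0.33 and Apoe by 0.28.

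Several cell type and stress lists ranked higher on the HF/HS diet. In the macrophage list 8 of 14 markers rose, 8 also adjusted over the list alone (median 0.27, adjusted p = 3.68e-05, but adjusted p = 0.404 with an estimated correlation). Mmp12 rose by 0.94, Gpnmb by 0.92, Trem2 by 0.44 and Cd5l by 0.36. In the stellate cell and extracellular matrix list 8 of 16 rose and 1 fell, over all genes and adjusted over the list alone (adjusted p = 0.00975, but adjusted p = 0.46 with an estimated correlation). Its collagen genes Col3a1, Col1a1, Col1a2 and Col4a1 rose by 0.58, 0.40, 0.34 and 0.22, and Col5a2 fell by 0.19. In the oxidative stress list 8 of 15 rose, 8 also adjusted over the list alone (adjusted p = 0.00111, but adjusted p = 0.404 with an estimated correlation), with Gsta1 at 0.91, Gsta2 at 0.76, Srxn1 at 0.34 and Gpx1 at 0.28. In the xenobiotic metabolism list 8 of 14 rose, and 10 adjusted over the list alone (adjusted p = 0.00251, but adjusted p = 0.404 with an estimated correlation). Besides Cyp3a11, Cyp2b10 rose by 0.53, Cyp2c29 by 0.31 and Cyp2c55 by 0.29. Members of the glutathione transferase and P450 families share reads, so which paralog changed is uncertain.

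The other lists did not pass the camera test for the effect over all strains. Metabolic lists among them were bile acids (2 rose, 1 fell of 16, adjusted p = 0.561), lipoproteins (4 and 4 of 16, adjusted p = 0.614), carbohydrate metabolism (1 and 5 of 19, adjusted p = 0.102), one-carbon metabolism (2 and 6 of 18, adjusted p = 0.106) and the respiratory chain (0 and 3 of 20, adjusted p = 0.122). Among their members, Abcb4 and Hsd3b7 rose by 0.41 and 0.21, and Slc10a1 and Pemt fell by 0.27 and 0.34. Cell type lists among them were lymphocytes (0 of 3, adjusted p = 0.895), neutrophils (0 of 7, adjusted p = 0.377), red blood cells (1 rose of 6, adjusted p = 0.895), endothelium (3 rose of 11, adjusted p = 0.728), bile duct (1 rose of 5, adjusted p = 0.395) and hepatocytes (3 rose, 7 fell of 11, adjusted p = 0.0563). The bile duct member Spp1 rose by 0.41. Stress lists among them were acute phase (2 rose, 5 fell of 16, adjusted p = 0.561), cytokines (4 rose of 11, adjusted p = 0.0537), interferon response (6 rose, 1 fell of 20, adjusted p = 0.148) and ER stress (2 and 3 of 16, adjusted p = 0.895). In the acute-phase list Saa3 rose by 0.76, and Apcs and Fgb fell by 0.51 and 0.25. The remaining lists were male-biased genes (4 and 4 of 16, adjusted p = 1), female-biased genes (1 and 7 of 20, adjusted p = 0.0759), sex-chromosome genes (0 of 5, adjusted p = 0.799), clock genes (2 and 4 of 17, adjusted p = 0.302), cell division (0 of 10, adjusted p = 0.614), fetal liver genes (1 rose of 5, adjusted p = 0.377) and RNAs without a poly(A) tail (4 and 2 of 12, adjusted p = 0.615). In the clock list Nr1d1 rose by 0.48, and Cry1 and Per2 fell by 0.44 and 0.29. Adjusted over the list alone, the counts that differed were lipoproteins (4 and 5), endothelium (2 rose), acute phase (3 and 6), one-carbon metabolism (3 and 8) and the respiratory chain (2 fell). Median and mean differed in sign for acute phase (-0.14 and 0.09, test down), endothelium (-0.02 and 0.02) and ER stress (-0.01 and 0.03), and for male-biased genes the median was -0.02 while the test pointed up. Of 2 lists with 1 tested member each, the pancreas marker Amy2a5 was not called (adjusted p = 0.994), and the fat cell marker Cfd, listed at 0 in 52 of 118 libraries, rose (adjusted p = 0.000247).

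The next question was what each sex did on the diet. In both, Adam11 and Cyp3a11 rose and Sqle, Idi1 and Cyp51 fell. In females 1171 genes rose and 986 fell, and in males 1343 rose and 1212 fell. With the strain as the unit, 556 genes were called in females and 685 in males. In the fit over all libraries, 565 rose in both sexes (129 expected if the calls were independent) and 486 fell in both (97.9 expected), and 4 changed in opposite directions. Across genes, which are not independent replicates, the effects had a Pearson r of 0.503. Without female control 1 the female count was 1436, and without female HF/HS 3 it was 1397.

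In females Adam11 rose by 1.63 ± 0.0926 (adjusted p = 2.1e-25), from 1.20 ± 0.972 to 8.25 ± 11.5 (SD, n = 29 and 29), and Cyp3a11 by 1.53 ± 0.188 (adjusted p = 1.27e-09). Ly6d rose by 1.72 ± 0.254 (adjusted p = 3.07e-07, with the strain as the unit 0.0861). Serpinb1a rose by 1.24 ± 0.117 (adjusted p = 1e-13) and Elovl3, a fatty acid elongase gene, by 1.31 ± 0.222 (adjusted p = 7.5e-06), from 8.17 ± 15.4 to 27.2 ± 56.7. Sqle fell by 2.06 ± 0.203 (adjusted p = 6.14e-13), Idi1 by 1.90 ± 0.157 (adjusted p = 6.33e-16) and Cyp51 by 1.72 ± 0.155 (adjusted p = 1.75e-14). Snora41 and Mup10, listed at 0 in 44 and 81 of 118 libraries, were called lower (adjusted p = 0.000637 and 1.46e-05), but not with the strain as the unit (adjusted p = 0.0539 and 0.533). Whether zeros of Mup10 are failed estimates is not known, so its direction is uncertain. In males Sqle fell by 3.37 ± 0.199 (adjusted p = 2.4e-24), from 61.6 ± 33.0 to 6.99 ± 8.82 (n = 30 and 30). Fdps fell by 2.30 ± 0.192, Idi1 by 2.28 ± 0.153, Fabp5 by 2.24 ± 0.219 and Cyp51 fell by 2.104 ± 0.151. Adam11 rose by 1.71 ± 0.0904 (adjusted p = 1.67e-27), Cyp3a11 by 1.54 ± 0.183, Mogat1 by 1.43 ± 0.118 and Vnn1 by 1.36 ± 0.162. Cyp4a10, a target of PPAR-alpha, rose by 1.45 ± 0.291 (adjusted p = 8.14e-05).

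In females 23 of 24 cholesterol genes fell and in males all 24, and adjusted over the list alone 24 fell in each sex (adjusted p = 8.04e-46 and 2.34e-65, and adjusted p = 0.00387 and 0.000201 with an estimated correlation). Lipid droplet genes rose in females (8 of 18, 9 adjusted over the list alone, adjusted p = 5.39e-07) and in males (12, or 13 adjusted over the list alone, adjusted p = 3.32e-11), and both held (adjusted p = 0.0265 and 0.00249 with an estimated correlation). LXR targets rose in females (6 of 9, 7 adjusted over the list alone, adjusted p = 5.5e-05) and in males (5, or 6 adjusted over the list alone, adjusted p = 7.01e-05), and both held as well (adjusted p = 0.00487 and 0.00377 with an estimated correlation). The female-biased list fell in females (10 of 20 fell, 12 adjusted over the list alone, median -0.59, adjusted p = 5.39e-07, but adjusted p = 0.244 with an estimated correlation). In males 6 of these rose and 3 fell, and the list was not called (adjusted p = 0.375). The interferon list rose in females (7 of 20, 10 adjusted over the list alone, adjusted p = 0.000111, but adjusted p = 0.472 with an estimated correlation), and in males 0 rose and 1 fell (adjusted p = 0.531). Fatty acid synthesis genes fell in males (14 of 19, 15 adjusted over the list alone, adjusted p = 2.84e-12, but adjusted p = 0.148 with an estimated correlation), and in females 1 rose and 1 fell (adjusted p = 0.0975).

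Fatty acid oxidation genes rose in males (21 of 26, 21 adjusted over the list alone, adjusted p = 7.35e-15, but adjusted p = 0.148 with an estimated correlation). In females 5 rose, and 6 adjusted over the list alone (adjusted p = 0.00411, but adjusted p = 0.682 with an estimated correlation). Macrophage markers rose in females (6 of 14, 10 adjusted over the list alone, adjusted p = 1.05e-06, but adjusted p = 0.244 with an estimated correlation) and in males (4, adjusted p = 0.00848, but adjusted p = 0.703 with an estimated correlation). The stellate list rose in females (7 of 16, adjusted p = 0.0497, but adjusted p = 0.644 with an estimated correlation) and in males (5 rose, 1 fell, adjusted p = 0.00982, but adjusted p = 0.557 with an estimated correlation). The oxidative stress list rose in females (5 of 15, adjusted p = 0.000801, but adjusted p = 0.244 with an estimated correlation) and in males (6, adjusted p = 0.0104, but adjusted p = 0.557 with an estimated correlation). Only in females were hepatocyte genes (5 of 11 fell, adjusted p = 0.0121, but adjusted p = 0.244 with an estimated correlation) and cytokines (3 of 11 rose, 6 adjusted over the list alone, adjusted p = 0.0186, but adjusted p = 0.564 with an estimated correlation) called. Only in males was the xenobiotic list called (8 of 14 rose, adjusted p = 0.000135, but adjusted p = 0.254 with an estimated correlation). A list called in 1 sex alone is not by itself a difference between the sexes, which the interaction tests.

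Whether the diet effect differed between the sexes was tested directly, as the male minus the female effect. It differed for 107 of 12205 genes, 45 higher and 62 lower in males, and 1406 genes had an unadjusted p below 0.05. With the strain as the unit 0 genes were called in limma, and 710 had an unadjusted p below 0.05, where 610 would by chance. The count was 60 without female HF/HS 3, 62 without male control 1, 36 without male HF/HS 2, 63 without male HF/HS 3 and 58 without the CC003 and CC060 libraries. Which direction had more genes was not stable: 39 were higher and 19 lower in males without CC003 and CC060, 55 and 39 without female control 1, 38 and 37 without female HF/HS 2, 33 and 30 without male HF/HS 3, and 62 and 57 with no filter. Sqle and Fabp5 fell further in males. The female-biased genes Cyp3a44 and Cyp3a16 moved in opposite directions, but P450 paralogs share reads, so their male rise is uncertain.

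Sqle had a difference of -1.31 ± 0.284 (adjusted p = 0.00727), since it fell by 2.06 in females and by 3.37 in males. Without male HF/HS 2 its adjusted p was 0.0515. Fabp5 had -1.29 ± 0.314 (adjusted p = 0.0207), from -0.95 in females and -2.24 in males, and was not called without female HF/HS 2 (0.0749), male control 1 (0.0891), male HF/HS 1 (0.113) or male HF/HS 2 (0.0688). Chrna4, a nicotinic receptor subunit gene, had -1.18 ± 0.267 (adjusted p = 0.0105), from -0.59 and -1.77, and was not called without female HF/HS 3 (0.0569) or male HF/HS 2 (0.0578). Tff3 had -1.81 ± 0.225 (adjusted p = 4.08e-08). It fell by 1.77 in males and was not called in females (adjusted p = 0.897), and it was listed at 0 in 33 of 118 libraries. Elovl3 had -1.57 ± 0.310 (adjusted p = 0.0017) and rose in females alone (male adjusted p = 0.456). Cyp3a44, a P450 gene with higher levels in female liver, had 1.95 ± 0.281 (adjusted p = 2.36e-06): it fell by 0.91 in females, from 775 ± 427 to 542 ± 516 (SD, n = 29 and 29), and rose by 1.04 in males, from 8.06 ± 8.10 to 14.8 ± 7.51 (n = 30 and 30). Cyp3a16 had 1.80 ± 0.283 (adjusted p = 1.86e-05), from -0.83 and 0.97. Their paralog Cyp3a11 rose in males from 1111 ± 1252 to 2630 ± 1544. Whether shared reads lay behind the male rise of Cyp3a44 and Cyp3a16 was not tested. Hsd3b1, a steroid dehydrogenase gene, had 1.55 ± 0.193 (adjusted p = 4.08e-08). It fell by 1.58 in females and was not called in males (adjusted p = 0.928), and it was listed at 0 in 22 of 118 libraries. Its male means were 0.711 ± 1.075 on the control and 0.659 ± 0.958 on the HF/HS diet, against 11.8 ± 15.3 in control females. On the log2(value + 1) scale such low male values left little room for a fall, so a response that males lack was not shown. Mup10, at 0 in 81 of 118 libraries, was called (adjusted p = 0.0162) but is given no size. It was not called in 8 of the 12 leave-out settings (0.0501 to 0.0724), and had an adjusted p of 0.286 with all 120 columns. None of these 9 genes was called with the strain as the unit, with adjusted p from 0.147 for Cyp3a44 and Hsd3b1 to 0.875 for Mup10. Without the CC003 and CC060 libraries, Sqle (0.0553), Fabp5 (0.167) and Chrna4 (0.432) were not called.

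**Figure D2:**
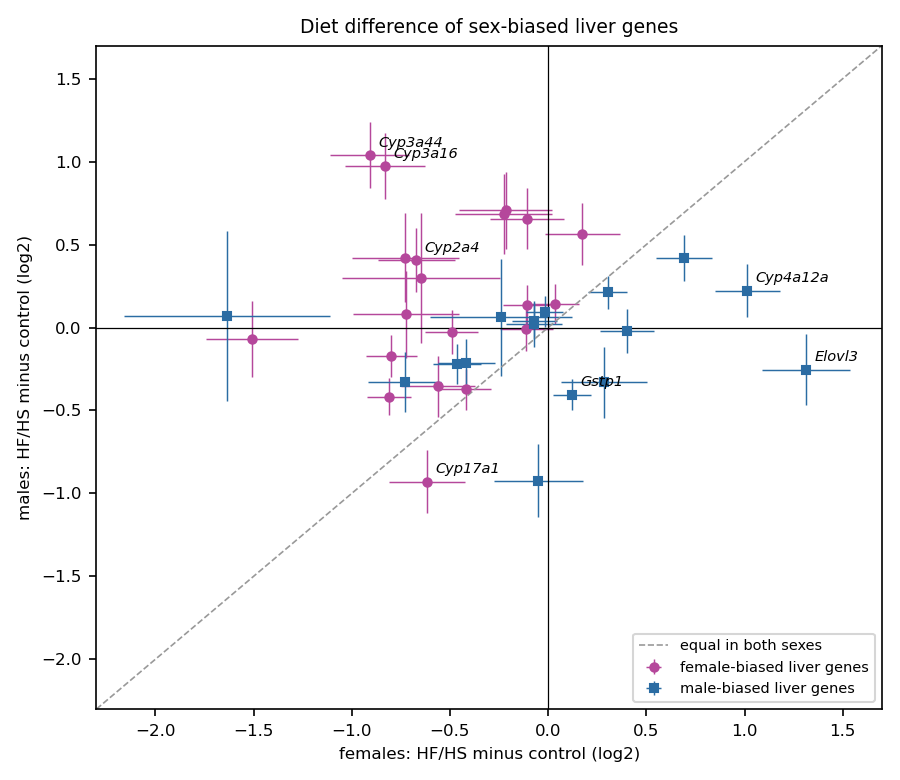
Diet difference (HF/HS minus control, log2 ± SE) in females on the x axis and in males on the y axis, for female-biased genes as circles and male-biased genes as squares, with a dashed line where both sexes would be equal. Cyp3a44 lies at -0.91 in females and 1.04 in males.

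By list, the diet effect was lower in males for cholesterol synthesis and uptake (4 of 24 called lower, 11 adjusted over the list alone, adjusted p = 6.34e-14, but adjusted p = 0.309 with an estimated correlation), with Pmvk at -0.76, Sc5d at -0.61 and Tm7sf2 at -0.53. Fatty acid synthesis was also lower in males (3 of 19, 11 adjusted over the list alone, adjusted p = 4.33e-12, but adjusted p = 0.309 with an estimated correlation), with Me1 at -1.01 and Acacb at -0.94. CC042 went the other way in both lists. Its means in females and males were -1.772 and -0.661 for cholesterol, and -1.165 and 0.306 for fatty acid synthesis. In CC011 and CC032 the fatty acid synthesis mean was also higher in males. The interferon list was lower in males (1 of 20, 4 adjusted over the list alone, adjusted p = 2.34e-08, but adjusted p = 0.312 with an estimated correlation), with Irf7 at -0.42 (adjusted p = 0.0451). Higher in males was fatty acid oxidation and PPAR-alpha targets (1 of 26, 9 adjusted over the list alone, adjusted p = 8.95e-11, but adjusted p = 0.358 with an estimated correlation), with Aldh3a2 at 0.71. So were female-biased genes (4 of 20, 11 adjusted over the list alone, adjusted p = 2.71e-13, but adjusted p = 0.241 with an estimated correlation), with Cyp2a4 at 1.08. Lipid droplet genes (1 of 18, adjusted p = 0.0266, but adjusted p = 0.62 with an estimated correlation) and xenobiotic genes (0 of 14, or 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.014, but adjusted p = 0.692 with an estimated correlation) also ranked higher in males. By list means, CC019, CC040, CC041 and CC042 went the other way for the interferon list. CC032 and CC043 did so for fatty acid oxidation, and CC003 and CC040 for female-biased genes. For lipid droplet genes CC003, CC011, CC032 and CC043 did so, and for xenobiotic genes CC003, CC019 and CC040.

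The series asked how the response varies between strains, so the diet effect was next taken within each strain. Adam11 was called in all 10 strains, Sqle, Idi1, Cyp51, Msmo1, Hsd17b7 and Rdh11 fell in 9, Cyp3a11 rose in 8 and Cd36 rose in 7. These recurrent genes were chosen after their values were seen. The number of genes called was 1634 in CC060, 1195 in CC003, 737 in CC043, 680 in CC032, 551 in CC042, 537 in CC041, 104 in CC019, 50 in CC013, 49 in CC040 and 24 in CC011. More genes fell than rose in CC060 (731 rose, 903 fell), but after quantile normalization 894 rose and 645 fell there. Over the 20 strain-sex groups, with 3 libraries per diet except for fewer in CC040 females, the median was 139.5 genes, from 3 in CC013 females to 2685 in CC060 males.

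These counts depended on the libraries left out and on the spread used. Unless said otherwise, leaving out a number dropped it from all 10 strains at once, which also changed the shared spread. With CC060 male control 3 alone left out, 891 genes were called in CC060 and 254 in CC060 males. With the strain's own libraries alone, 40 genes were called in CC060, 145 in CC003, 2 in CC011, 188 in CC013, 1476 in CC032, 841 in CC041, 2160 in CC042 and 1417 in CC043. Without male control 3 of every strain the CC060 count was 904, without male control 1 it was 3053 and without male HF/HS 2 it was 1056. The median over groups was 60.5 without male HF/HS 3. In CC011 it was 14 without female control 2, 39 without female HF/HS 1, 58 without female HF/HS 2, 59 without female HF/HS 3, 12 without male control 1, 4 without male control 3, 12 without male HF/HS 1 and 7 without male HF/HS 2. For CC013, 33 genes were called without male control 2 and 29 without male HF/HS 2, and for CC019 there were 55 without male control 1. For CC032, 448 were called without male HF/HS 2 and 420 without male HF/HS 3. For CC040, 26 were called without female control 1, 75 without female HF/HS 1, 112 without female HF/HS 2 and 32 without male HF/HS 3. For CC041 the counts were 352, 315 and 271 without female control 1, female control 2 and female HF/HS 3, and 349, 352, 304 and 215 without male control 1, male control 2, male HF/HS 1 and male HF/HS 2. For CC042, 294 were called without female HF/HS 3, 361 without male HF/HS 1 and 319 without male HF/HS 2. For CC043, 467 were called without female control 2, 467 without female control 3, 462 without female HF/HS 3 and 264 without male HF/HS 3.

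**Figure D3:**
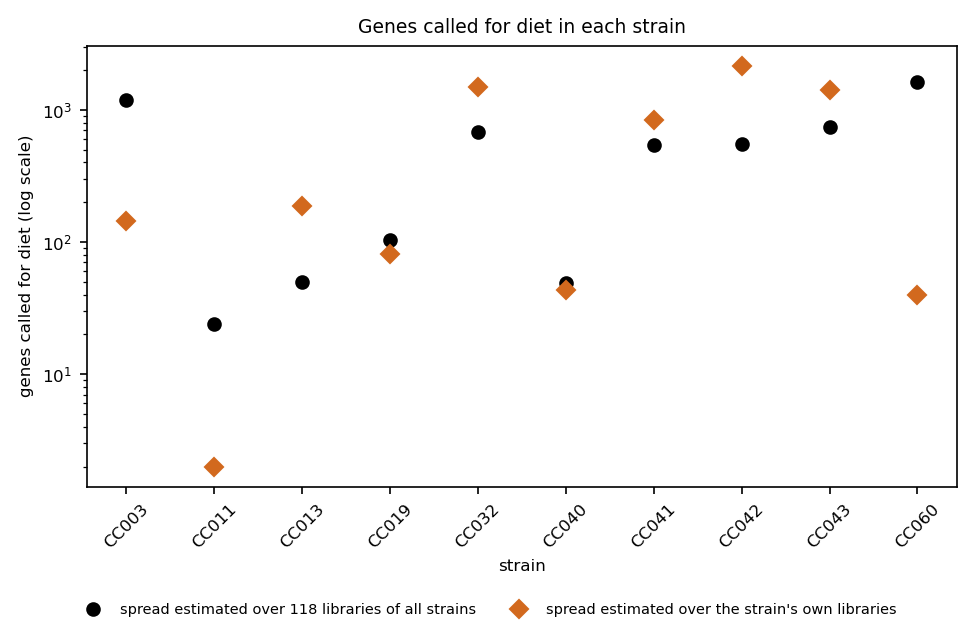
Genes called for the diet effect in each strain (y axis, log scale), with the spread taken over the 118 libraries of all strains (black circles) or over the strain's own libraries (orange diamonds). CC060 had 1634 by the former and 40 by the latter.

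In CC060 Adam11 rose by 3.31 ± 0.202 (adjusted p = 9.86e-24), from 5.16 ± 4.31 to 55.3 ± 20.7 (SD, n = 6 and 6 as in all strains but CC040), and Krt23 by 2.63 ± 0.466 (adjusted p = 4.36e-05). In CC019 Sqle fell by 4.02 ± 0.444 (adjusted p = 1.75e-10), from 62.3 ± 31.2 to 3.18 ± 3.17, and Adam11 rose by 2.199 ± 0.202 (adjusted p = 1.83e-13). Cyp3a11 rose there by 1.66 ± 0.410 (adjusted p = 0.0193), but not with that strain's own libraries alone (0.104), after quantile normalization (0.0649) or without female control 1 (0.155), female HF/HS 2 (0.0705), male control 1 (0.0599), male HF/HS 2 (0.116) or male HF/HS 3 (0.0618). In CC032 Ly6d rose by 3.91 ± 0.554 (adjusted p = 2.76e-07), from 8.91 ± 9.06 to 120 ± 54.8, Sqle fell by 2.94 ± 0.444 and Idi1 by 2.75 ± 0.343. In CC043 Ly6d rose by 3.44 ± 0.554 (adjusted p = 2e-05) and the interferon-related gene Ifi27l2b by 2.49 ± 0.310 (adjusted p = 3.76e-08), from 2.43 ± 0.603 to 21.8 ± 13.2. In CC041 Cd36 rose by 2.18 ± 0.201 (adjusted p = 2.17e-13), from 19.6 ± 10.1 to 86.6 ± 19.9, and Sqle fell by 3.10 ± 0.444. Sult1e1, an estrogen sulfotransferase gene at 0 in 13 of 118 libraries, rose there by 2.27 ± 0.487 (adjusted p = 0.00181). In CC042 the lipid droplet gene Fitm1 rose by 2.24 ± 0.321 (adjusted p = 4.33e-07), from 5.17 ± 4.78 to 46.5 ± 45.4. Cyp4a10 rose there by 2.31 ± 0.650 (adjusted p = 0.0216), but not in 6 of the 12 leave-out settings (0.0543 to 0.0783).

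In CC003 Cidec rose by 2.34 ± 0.377 (adjusted p = 8.85e-06). In CC013 Cyp3a11 rose by 2.31 ± 0.410 (adjusted p = 3e-04), from 150 ± 98.5 to 727 ± 543, and Adam11 by 1.54 ± 0.202, while Sqle fell by 2.21 ± 0.444 and Idi1 by 2.14 ± 0.343. In CC011 Mogat1 rose by 1.49 ± 0.264 (adjusted p = 0.00135) and Cd36 by 1.09 ± 0.201 (adjusted p = 0.00208), but neither with that strain's own libraries alone (adjusted p = 0.632 and 0.67). In CC040, with 5 libraries per diet, the macrophage gene Gpnmb rose by 1.72 ± 0.318 (adjusted p = 0.00123), and Sqle fell by 2.34 ± 0.496 (adjusted p = 0.00606). With the strain's own libraries alone, Gpnmb in CC040 and Cyp3a11 in CC013 were not called (adjusted p = 0.0578 and 0.098). Cyp2b10 rose there by 1.91 ± 0.477 (adjusted p = 0.0379), but not in 7 of the 12 leave-out settings (0.059 to 0.275), with a pseudocount of 5 (0.268), with the strain's own libraries alone (0.223) or with all 120 columns (0.0555). The rule also took genes that were listed at 0 in many of the 118 libraries, for which no size of change is given. Those that rose were Rprl2 in CC003 (at 0 in 32) and Cfd in CC032 (at 0 in 52). Those listed lower on the HF/HS diet were Snora31 and Snora52 in CC003 (at 0 in 33 and 32), Snord61 and Mup7 in CC011 (113 and 71), Mup10 in CC019 (81), Mir1948 in CC040 (117), Mir684-2 in CC041 (51), Snora41 and Mup10 in CC042 (44 and 81), Snord45c and Mir15a in CC043 (108 and 115), and Mup9 and Mup1 in CC060 (57 and 58). Since a 0 can mark a gene that could not be estimated, the direction of change is uncertain too for the Mup genes. Mup10 had an HF/HS mean of 0 in CC019 and CC042, with control means of 898 and 1648. Among the genes listed at 0 in many libraries, Snora52 was not called without female HF/HS 2 (0.0523), female HF/HS 3 (0.0532) or male HF/HS 3 (0.124), and Mup9 not without female HF/HS 2 (0.138) or female HF/HS 3 (0.126). Snord61 was not called without female control 2 (0.245), male control 1 (0.261), male control 3 (0.241) or male HF/HS 1 (0.059), and Mir15a not without female control 1 (0.0798), male control 1 (0.206) or male HF/HS 3 (0.0557). Mir1948 had an adjusted p of 1 without female control 1, Mup7 was not called in 10 of the 12 leave-out settings (0.0955 to 0.174), and Mir684-2 not in 8 (0.0639 to 0.156). With the strain's own libraries alone, 10 of these genes were not called: Snora31 (0.121), Snora52 (0.331), Snord61 (1), Mup7 (1), Mir1948 (0.615), Mir684-2 (0.103), Snord45c in CC043 (0.103), Mir15a (0.382), Mup9 (0.571) and Mup1 (0.554). Snora31 and Snora52 were also not called with library weights (0.303 and 0.3), Mir684-2 not without a filter (0.0536), and Mir1948 and Mup7 not with all 120 columns (0.215 and 0.38). Mup7 was not called without the CC003 and CC060 libraries either (0.0676).

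Cholesterol synthesis and uptake fell in every strain by camera at the preset correlation, with list means from -0.54 in CC011 to -1.91 in CC019. In 4 strains it was not called otherwise (adjusted p = 0.0602 in CC041, 0.068 in CC043, 0.0864 in CC060 and 0.323 in CC011 with an estimated correlation). The number of its 24 members that fell was 23 in CC032, 20 in CC019 and CC060, 19 in CC003, CC041 and CC042, 17 in CC043, 11 in CC013, 5 in CC040 and 0 in CC011, and adjusted over the list alone it was 5 in CC011 and 19 to 24 elsewhere. The list was called with an estimated correlation in CC003, CC013, CC019, CC032, CC040 and CC042, with adjusted p = 6.16e-07 in CC019. Lipid droplet genes rose most in CC032 (10 of 18, 13 adjusted over the list alone, mean 0.95, adjusted p = 9.82e-17, and adjusted p = 0.000134 with an estimated correlation). The number that rose was 7 in CC043, 5 in CC003, 4 in CC041, CC042 and CC060, 2 in CC011, and 0 in CC013, CC019 and CC040. Macrophage markers rose in CC032 (5 of 14, adjusted p = 6.31e-09, but adjusted p = 0.134 with an estimated correlation), in CC041 (4, or 11 adjusted over the list alone, adjusted p = 2.41e-08, but adjusted p = 0.111 with an estimated correlation), in CC043 (4, or 8 adjusted over the list alone, adjusted p = 3.34e-08, but adjusted p = 0.14 with an estimated correlation) and in CC040 (3, or 5 adjusted over the list alone, adjusted p = 1.33e-06, but adjusted p = 0.171 with an estimated correlation). Differences between strains were not tested for whole lists.

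**Figure D4:**
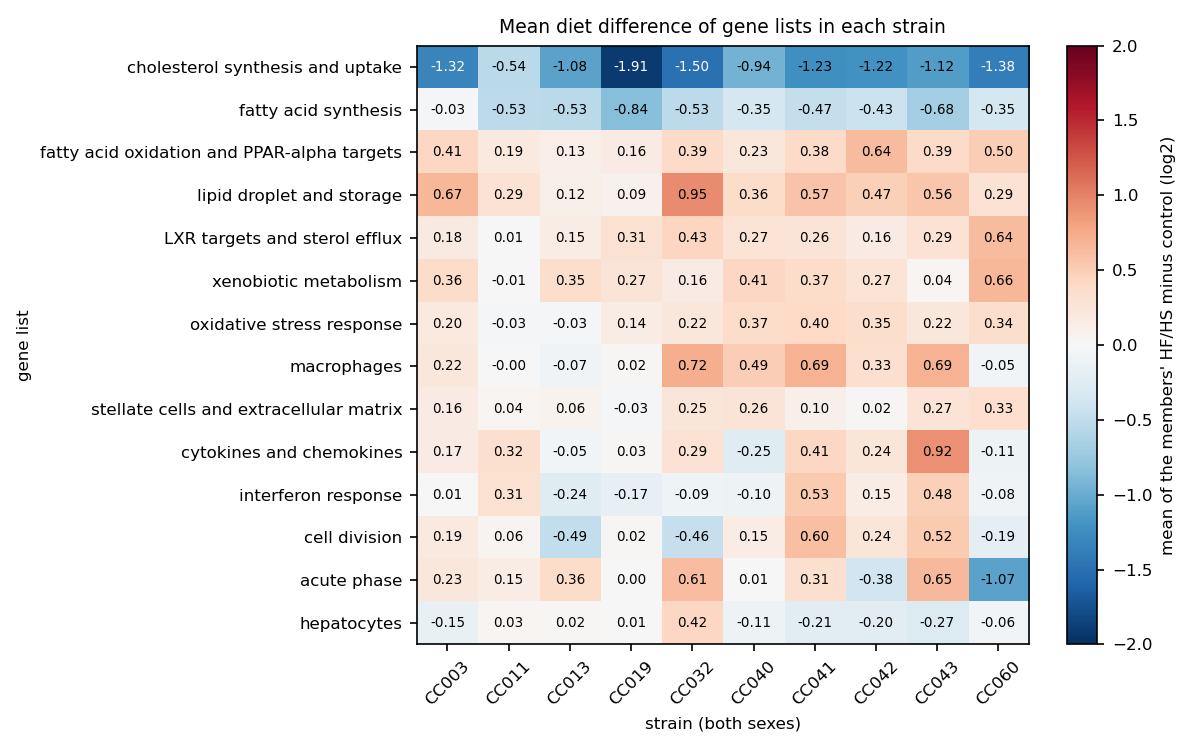
Mean diet effect (HF/HS minus control, log2, colour) of 14 gene lists (y axis) in 10 strains (x axis). Cholesterol synthesis and uptake had its lowest mean, -1.91, in CC019. The hepatocyte mean of 0.418 in CC032 came from 1.165 in males and -0.33 in females, and Alb was at 0 in 9 of 12 CC032 libraries.

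Whether the diet effect differed between strains was tested for each gene by the limma F test. It differed for 676 genes (5.54%), and 2455 had an unadjusted p below 0.05. The count was 440 without female control 3, 375 without male HF/HS 1, 338 without male HF/HS 2, 284 without male HF/HS 3, and 773 without the CC003 and CC060 libraries. It was 1093 with no filter, 448 with a filter 5 times higher, 1608 without the 3 libraries of the largest spread and 5125 with library weights. Among the genes the rule could name, the lowest p was that of Rubie, a long noncoding RNA (adjusted p = 1.58e-24, at 0 in 52 of 118 libraries). It fell by 3.63 ± 0.164 in CC060, from 26.6 ± 19.5 to 0.666 ± 0.221 (SD, n = 6 and 6), and was called in no other strain. Adam11 rose in all strains, by 0.73 ± 0.202 in CC042 and by 3.31 ± 0.202 in CC060 (adjusted p = 5.55e-09). The strain with the highest effect was CC032 for Fam83a with 1.96 ± 0.159, from 0.947 ± 0.522 to 7.25 ± 4.38 (adjusted p = 5.09e-12), for St6galnac2 with 1.69 ± 0.155, from 9.36 ± 4.76 to 31.9 ± 11.9 (adjusted p = 2.28e-09), and for Themis with 1.43 ± 0.137 (adjusted p = 3.11e-09). Fam83a rose in 5 strains, Themis in 4 and St6galnac2 in 1. Cidea, a lipid droplet gene at 0 in 53 of 118 libraries, rose only in CC032, from 1.21 ± 1.59 to 31.3 ± 38.5 (adjusted p = 7.3e-12). Aqp4, a water channel gene at 0 in 13 of 118 libraries, rose in 4 strains, most in CC042 with 1.81 ± 0.144, from 1.56 ± 1.34 to 9.72 ± 7.40 (adjusted p = 1.17e-10). Mgst2, at 0 in 51 of 118 libraries, rose in 2 strains (adjusted p = 1.82e-08, but 0.462 with a pseudocount of 0.1). Mup11 and Mup10, each at 0 in 81 of 118 libraries, had adjusted p of 3.29e-13 and 5.19e-11. Of the genes called over all strains, 1624 were called in no single strain, and 88 genes rose in 1 strain and fell in another. Across genes, which are not independent replicates, the diet effects of 2 strains had a Pearson r between 0.104 and 0.402 (median 0.223, 45 pairs), and those of the 2 sexes within a strain had an r between -0.106 in CC011 and 0.236 in CC041.

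The sexes were compared on the control diet to show the baseline on which the diet acted. The P450 genes Cyp4a12a and Cyp4a12b and the elongase gene Elovl3 were higher in males, and all female-biased list genes were higher in females. In all, 3021 genes were higher in males and 2293 in females, but with size factor scaling the balance turned, with 2476 higher in males and 2713 in females. Cyp4a12a was higher in males by 7.15 ± 0.164 (adjusted p = 3.54e-54), with 11.1 ± 38.8 in females and 445 ± 114 in males (SD, n = 29 and 30). Cyp4a12b was higher by 6.04 ± 0.139 (adjusted p = 2.86e-54), and these 2 paralogs share reads. Mup20, a major urinary protein gene, was higher by 5.98 ± 0.135 (adjusted p = 3.84e-55), Elovl3 by 5.84 ± 0.219 (adjusted p = 1.1e-38) and the Y-linked Eif2s3y by 5.68 ± 0.0580 (adjusted p = 2.21e-82). Mup1, Mup12, Mup9, Mup19 and Mup8 were listed lower in males, but were at 0 in 58, 57, 57, 56 and 54 of 118 libraries, so no difference is given.

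All 20 female-biased list genes were lower in males (adjusted p = 8.03e-61, and adjusted p = 2.1e-06 with an estimated correlation), with Slc22a26 at -5.69 and the P450 gene Cyp3a41b at -7.73. Of 16 male-biased genes 14 were higher and 2 lower in males (adjusted p = 4.12e-24, and adjusted p = 3.22e-06 with an estimated correlation). Sex-chromosome genes were called (4 higher, 1 lower of 5, adjusted p = 1.14e-10, and adjusted p = 2.61e-05 with an estimated correlation). Fatty acid oxidation and PPAR-alpha targets were lower in males (17 of 26 lower, 1 higher, adjusted p = 7.06e-06, but adjusted p = 0.685 with an estimated correlation), with Vnn1 at -2.05, Acot2 at -1.47, Cyp4a10 at -3.31 and Cyp4a14 at -3.14. Endothelial markers (9 of 11 lower, adjusted p = 0.00327) and interferon response genes (10 of 20 lower, 1 higher, adjusted p = 0.0035) were lower, but were not called with an estimated correlation (adjusted p = 0.533 and 0.685 with an estimated correlation). Macrophage markers (9 of 14 lower, adjusted p = 0.0159) and cytokines (7 of 11 lower, 8 adjusted over the list alone, adjusted p = 0.0336) were lower too, but each had an adjusted p = 0.685 with an estimated correlation. Respiratory chain (14 of 20 higher, 16 adjusted over the list alone, adjusted p = 0.000575) and ER stress genes (10 of 16 higher, adjusted p = 0.0304) were higher in males, and the xenobiotic list was lower (5 higher, 8 lower of 14, adjusted p = 0.0159). These 3 lists were not called with an estimated correlation (adjusted p = 0.685 with an estimated correlation for each). On the HF/HS diet 3065 genes were higher in males and 2480 in females, but 2529 and 2893 with size factor scaling. There 14 of 24 cholesterol genes were lower in males (adjusted p = 0.000426, but adjusted p = 0.798 with an estimated correlation), and 19 of 20 interferon genes were lower (adjusted p = 1.24e-08, but adjusted p = 0.278 with an estimated correlation).

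Strains were compared on the control diet to show how far they differed before the diet. By the F test the values of 11796 of 12205 genes differed (96.6%), or 11452 without CC003 and CC060. Reads of all strains were mapped to mm10, and an effect of strain sequence or gene copies on these values was not tested. The complement gene C1s1 was lowest in CC013 with 0.300 ± 0.131 and highest in CC042 with 351 ± 37.1 (SD, n = 6 and 6; adjusted p = 4.91e-81). The carboxylesterase gene Ces2h was at 0.291 ± 0.206 in CC042 and at 116 ± 17.8 in CC019 (adjusted p = 5.75e-71). Cwc22, a splicing factor gene, was at 4.93 ± 0.596 in CC013 and at 288 ± 15.8 in CC042 (adjusted p = 4.67e-70). The other 7 of the 10 lowest p that the rule took were those of RNAs without a poly(A) tail (Snora74a, Snord104, Scarna13, Rpph1, Rnu12, Rprl3 and Scarna6), all lowest in CC060. They had adjusted p from 1.8e-92 for Snora74a to 5.89e-70 for Scarna6, and their differences cannot be told apart from library preparation.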

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

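Which tests were chosen when: the CC060 tests, the hepatocyte test and the test of Mup genes in CC003 were written after the result was seen, and the other tests on Mup genes and those on paralogs and failed zeros before. A result is listed here because a test of the difference between sexes or between strains passed. The diet effect differed between the sexes for 107 genes and between the strains for 676. By gene, the male minus female diet effect (log2) was 1.948 for Cyp3a44, 1.802 for Cyp3a16, 1.784 for Mup10 and 1.554 for Hsd3b1. The value of Mup10 is no measured fold, since it was listed at 0 in 81 of 118 libraries. For Hsd3b1, low male values left little room for a fall in males, as given above. The male minus female effect was -1.806 for Tff3, -1.568 for Elovl3, -1.309 for Sqle, -1.292 for Fabp5 and -1.184 for Chrna4. By list, the camera test of the difference between the sexes had an adjusted p of 6.34e-14 for cholesterol synthesis and uptake, 4.33e-12 for fatty acid synthesis, 8.95e-11 for fatty acid oxidation and PPAR-alpha targets, 0.0266 for lipid droplets and storage, 2.34e-08 for the interferon response, 0.014 for xenobiotic metabolism and 2.71e-13 for female-biased genes. None of these 7 lists was called with an estimated correlation. For differences between strains, the F test gave an adjusted p of 1.58e-24 for Rubie, 3.29e-13 for Mup11, 5.09e-12 for Fam83a, 7.3e-12 for Cidea, 5.19e-11 for Mup10, 1.17e-10 for Aqp4, 2.28e-09 for St6galnac2, 3.11e-09 for Themis, 5.55e-09 for Adam11 and 1.82e-08 for Mgst2.

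In the main fit the count of diet calls was higher in CC060 than in the other 9 strains. At least part of the count may rest on 1 library, since 891 genes were called instead of 1634 with CC060 male control 3 alone left out. The rank was not stable. With male control 3 of every strain left out, CC060 had 904 and CC003 1570, and with no filter they had 1520 and 2086. A larger spread between CC060 libraries stayed undecided, since the ratio of its median spread to that of the other strains was 1.02, while a fit on its own libraries called 40 genes, as a larger spread would need. For that test the root mean square (ratio 1.13, larger than 7 of 9 strains) had been put in place of the median after values were seen, and the median, which was written first, was restored. A response shared by both sexes stayed undecided: 55.9% of genes called in CC060 males had the same sign in CC060 females, below the lowest other strain (62.3%, CC003), but without that library it was 74.4%, and the r between the sexes in CC060 (0.122) was above that of 4 strains. This explanation was narrowed from a diet response of the strain after its value was seen, so a response of CC060 males alone stays open.

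The genes Mup1, Mup12, Mup9, Mup19 and Mup8 were listed lower in males on the control diet, although major urinary proteins are abundant in male liver. Of 150 male values 132 were 0, and 100% of the 18 others lay above 100, as the test of failed estimates stored as 0 needed, and the median of these 18 was 4.12 times that of the female values above 0, which the other test was planned to count against a lower level in males. Both plans were wrong, since 15 of the 18 male values came from CC003, where no male value was 0, so the tests compared strains and library types. Failed estimates and a lower level in males of the other strains stay open. Within CC003 a lower level was not borne out, since the ratio of male to female medians was 4.58 and in all 5 genes every male value lay above every female value (n = 3 and 3).

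Of 20 female-biased genes, 10 fell in females on the HF/HS diet (median -0.588, adjusted p = 5.39e-07, but adjusted p = 0.244 with an estimated correlation), and the mean of the list was below 0 in females of 9 strains. Reads shared between Cyp2 and Cyp3a paralogs were not borne out as the whole cause, because the median was -0.649 in the 11 members outside these families. For the members inside these families, and for paralogs of other families, shared reads stay open. Hepatocyte genes fell too (5 of 11, median -0.153, adjusted p = 0.0121, but adjusted p = 0.244 with an estimated correlation). Their median was higher by 0.435, so a lower share of hepatocytes was not borne out as the whole cause and stays open for a part. Failed zeros could not be decided, since the filter kept all 20 members and left -0.588 unchanged.

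Other splits of the same libraries were drawn to compare the real grouping with other groupings. Each split relabelled all strains at once, so real effects could enter the shared spread and lower the other counts. The splits alone therefore do not exclude chance. In the following results only the real grouping (1 of 100 splits, or of 60 for CC040) called as many genes. This held for the effect over all strains (3975, highest other split 4), in females (2157, 129), in males (2555, 8), for the difference between sexes (107, 10) and between strains (676, 81), for sex on the control diet (5314, 225), sex on the HF/HS diet (5545, 109), strains on the control diet (11796, 29) and the median over groups (139.5, 11). By strain it held for CC003 (1195, 498), CC013 (50, 7), CC019 (104, 14), CC032 (680, 173), CC040 (49, 13), CC041 (537, 411), CC042 (551, 73), CC043 (737, 46) and CC060 (1634, 1518). For CC060 and CC041 this margin was narrow: without CC060 male control 3 alone 891 genes were called in CC060, and in 7 of the 12 leave-out settings 215 to 352 were called in CC041, fewer than their highest other splits. For the difference between sexes the splits cover only the spread between libraries, and with the strain as the unit 0 genes were called (710 with an unadjusted p below 0.05, where 610 would by chance). In CC003 and CC060 the median of the other splits was 252 and 182 genes, so other splits of these samples called many genes too. CC003 had the largest median spread of all strains (0.472), and for CC060 a larger spread stayed undecided, as given above. Whether spread or another structure of the samples lay behind the calls of the other splits was not tested. For CC011 the real grouping was not set apart even by this measure, since 10 of 100 splits called at least 24 genes, with up to 373.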

How the results depend on the processing

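Of 3165 values of 120 gene results under the alternatives, 3026 kept their side of the threshold, 139 lost their call and 0 reversed, but Mir1948 in CC040 had a difference of 0, and so no direction, in 2 of them. The 120 results were picked as called in the main fit, with the largest changes or lowest p. None could therefore gain a call, and the share kept does not measure the stability of other genes. Pseudocounts, size factors and a prior without trend moved no count of genes by more than 1.5 times, but size factors turned the balance between the sexes (2476 higher and 2713 lower in males on the control diet, 2529 and 2893 on the HF/HS diet). The depth is unknown, so what depth limits could not be measured. Without a filter (20952 genes tested) the counts were 1093 for the difference between strains, 2086 in CC003, 40 in CC011, 94 in CC013, 201 in CC040 and a median of 267.5 over groups. With a filter 5 times higher (8704 tested) they were 448 for the difference between strains, 691 in CC003, 14 in CC011 and 27 in CC040, where fewer genes were tested by construction. Quantile normalization gave 84 in CC040. The library number as a block within strain and sex gave 16 in CC040, where it ended the calls of Sqle (adjusted p = 0.346), Gpnmb (0.11), Cyp2b10 (0.336) and Mir1948 (difference 0, adjusted p = 1). This block also ended the calls of Cyp4a10 in CC042 (0.053) and Mup7 in CC011 (0.0897), and as a block over all groups it gave 54 in CC040. The numbers do not pair the libraries: the deviations of 58 same-numbered control and HF/HS pairs had a median r of -0.012 (0.014 for different numbers), 9 had an r above 0.1, and in 3 of 20 groups every control library correlated best with its own number. With the strain as the unit, 2072 genes were called over all strains, 556 in females, 685 in males and 0 for the difference between sexes. Here n fell to 10 strains by construction. With the strain's own libraries the counts were 145 in CC003, 2 in CC011, 188 in CC013, 1476 in CC032, 841 in CC041, 2160 in CC042, 1417 in CC043 and 40 in CC060. With an estimated correlation, 3 of the 9 list tests called over all strains held. Leaving out 1 library number gave 3402 to 4130 over all strains, 1397 to 2659 in females, 1845 to 2673 in males, 36 to 134 for the difference between sexes, 284 to 871 for that between strains, 4276 to 5395 for sex on the control diet, 4542 to 6011 for sex on the HF/HS diet and 11593 to 11814 for strains on the control diet. By strain the ranges were 885 to 1570 (CC003), 4 to 59 (CC011), 29 to 55 (CC013), 55 to 151 (CC019), 420 to 781 (CC032), 26 to 112 (CC040), 215 to 704 (CC041), 294 to 612 (CC042), 264 to 762 (CC043) and 904 to 3053 (CC060), and the median over groups was 60.5 to 164. The next alternatives were added after seeing the data. Without the 3 libraries of the largest spread (CC011 female HF/HS 1, CC060 male control 3, CC060 female control 1) the counts were 1608 for the difference between strains, 2070 in CC003, 60 in CC011, 116 in CC013, 248 in CC019, 1289 in CC032, 133 in CC040, 1298 in CC041, 1130 in CC042, 1602 in CC043 and a median of 366.5. With library weights they were 3498 in females, 4333 in males, 533 for the difference between sexes, 5125 for that between strains, 200 in CC003, 433 in CC011, 1186 in CC013, 844 in CC019, 3641 in CC032, 330 in CC040, 1807 in CC041, 3035 in CC042, 3765 in CC043 and a median of 839.5. Without CC003 and CC060 the difference between sexes had 58. With all 120 columns no count moved (38 in CC040), nor without the 300 genes with a 0 beside a high value. Except where the construction is named, the cause was not tested.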

Other observations

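The tests of relations over strains were written before their results were seen, and the strains and lists named here, with the fits that leave out CC060 libraries, were chosen after. Interferon response genes rose on the HF/HS diet in CC041 (9 of 20, 15 adjusted over the list alone, adjusted p = 1.78e-10, but adjusted p = 0.111 with an estimated correlation), with Gbp3 at 0.93, Ifit1 at 0.85, Irf7 at 0.83 and Bst2 at 0.52. Interferon genes rose in CC043 as well (9 of 20, 11 adjusted over the list alone, adjusted p = 2.88e-08, but adjusted p = 0.174 with an estimated correlation), with Irf7 at 0.86, Isg15 at 0.84, Gbp3 at 0.79 and Rsad2 at 0.75. Macrophage markers rose in both strains too (4 of 14 in each, list means 0.69, adjusted p = 0.111 in CC041 and 0.14 in CC043 with an estimated correlation), and cytokines ranked higher in both (list means 0.41 and 0.92, adjusted p = 0.488 and 0.068 with an estimated correlation). In CC011 the interferon list ranked higher with 0 genes called, and 4 adjusted over the list alone (adjusted p = 7.47e-10, but adjusted p = 0.323 with an estimated correlation). Its mean there was 0.495 in females and 0.127 in males. Acute-phase and cytokine means in these females were 0.883 and 1.011, and they include CC011 female HF/HS 1, the library of the largest spread (0.742). The interferon list ranked lower in CC019 with 0 called (adjusted p = 0.0133, but adjusted p = 0.898 with an estimated correlation). In CC013 it ranked lower with 0 genes called (adjusted p = 1.23e-05, but adjusted p = 0.483 with an estimated correlation). Cell division genes ranked higher in CC041 (2 of 10 rose, 8 adjusted over the list alone, adjusted p = 8.31e-06, but adjusted p = 0.27 with an estimated correlation), with Cdc20 at 1.07 and Cdk1 at 0.72. In CC043 Mcm5 rose by 0.92, Top2a by 0.91 and Mcm2 by 0.72 (adjusted p = 0.000187, but adjusted p = 0.288 with an estimated correlation). In CC032 Rrm2 fell by 0.88, Mcm5 by 0.87 and Pcna by 0.39 (adjusted p = 0.000349, but adjusted p = 0.444 with an estimated correlation). Acute-phase genes fell in CC060 (9 of 16, 10 adjusted over the list alone, adjusted p = 5.31e-06, but adjusted p = 0.369 with an estimated correlation), with Apcs at -1.57, Orm1 at -1.27, Itih4 at -0.78 and Crp at -0.58. Hemoglobin genes fell there too (Hbb-b2 -1.93, Hba-a2 -1.78 and Hba-a1 -1.76, adjusted p = 0.00371, but adjusted p = 0.369 with an estimated correlation), and these paralogs share reads. Among the control libraries of CC060, male control 3 and female control 1 were among the 3 libraries of the largest spread (0.703 and 0.614). Without male control 3 alone, 8 acute-phase genes and 2 red blood cell genes fell, and without the 3 libraries of the largest spread 11 and 1 fell. Both fits kept CC060 male control 2, whose highest row was the acute-phase gene Saa2 (4.97% of its total). The neutrophil list was not called in CC060 (mean -0.52, adjusted p = 0.263).

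The library CC011 female HF/HS 1 had the highest values of 120 libraries for Saa1 (99010, against 4107 and 416.6 in the others of its group and a median of 240.7), Saa2 (115000), Saa3 (47080), Lcn2 (21580) and Orm2 (7314). These are acute-phase genes, and Hp, another of them, was listed at 0 in this library. In the others of its group Hp had 7008 and 5753, with a median of 3592 over all libraries. Whether that 0 marks a failed estimate is not known.

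Over the 10 strains, the mean diet effect of the lipid droplet and storage list was related to those of 4 lists. With the macrophage list Pearson r was 0.774 (permutation p = 0.00757, adjusted p = 0.0303 by permutation) and Spearman rho was 0.782 (permutation p = 0.00995, adjusted 0.0398), which is consistent with the 2 responses varying together over strains. Without CC032 and CC019, the 2 farthest strains, r was 0.696, and without CC003 and CC060 it was 0.859. With lipid storage from 1 sex and macrophages from the other, r was 0.101 and 0.44, so shared libraries may account for part of the relation. For the stellate list r was 0.441 (permutation p = 0.202, adjusted 0.269; rho 0.418, permutation p = 0.233; r 0.12 without the 2 farthest). For cholesterol synthesis r was -0.0718 (permutation p = 0.849, adjusted 0.849; rho -0.212, permutation p = 0.558; r -0.411 without them). For PPAR-alpha targets r was 0.519 (permutation p = 0.122, adjusted 0.244; rho 0.576, permutation p = 0.0865; r 0.536 without them). The tests of these 3 were planned to count against a relation at an adjusted p of 0.05 or more, which was wrong, since a p that misses the threshold with 10 strains does not exclude a relation. They were labelled undecided after their values were seen.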
